A study of Mus musculus with 6 samples.

How the data were processed

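Total RNA was extracted with Trizol from snap-frozen bone marrow, labelled with biotin by the array maker's protocol and hybridised to Affymetrix arrays, 1 per sample, per the labels' protocols. The deposited table holds log2 expression values of 45101 probe sets in 6 arrays, already normalized between arrays before deposit: the upper quartiles of the arrays lay between 7.34 and 7.43. The submitters' processing notes name RMA and MAS5 without role, order or version, and the range of the log2 values, from 2.26 to 14.88, is that of a log scale and not of linear signals. Which of these tools made the table is not given in the sources used here, nor are scan dates or hybridization batches, and no detection calls were used here.

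Groups and replicate numbers were taken from the sample titles. The 64 control probe sets were left out of all tests, which leaves 45037. The platform's annotation gives 1 gene symbol to 34945 of these, several to 932 and none to 9160, which are unnamed here. Genes were matched by gene ID to a reference gene table of assembly GRCm38.p6, used only for names, chromosome, gene order and gene length, and 18032 of 18193 genes had a chromosome there. No coordinates are given, since the build behind the array's annotation is not stated in the sources used here. No per-sample column was left unused.

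The main test was limma's linear model with empirical Bayes moderation (limma 3.58.1 in R 4.3.3), AKR F1 minus DBA F1 over all 6 arrays with 4 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It was run on all probe sets and on 1 probe set per gene, the brightest by its mean over all 6 arrays among those with a single symbol. Of the 18193 genes 9010 have more than 1 such probe set. Gene lists were tested with camera with the correlation estimated from the data, adjusted over the 25 lists with at least 5 measured members. A further list of sex-linked genes was read as values only. The lists cover B cells, plasma cells, erythroid cells, neutrophil primary granules, neutrophil secondary granules, monocytes and macrophages, dendritic cells, T cells, NK cells, receptors of the NK gene complex, megakaryocytes, eosinophils with basophils and mast cells, stem and progenitor cells, stroma with bone and endothelium, osteoclasts, adipocytes, skeletal muscle, interferon response, MHC class I, MHC class II, proliferation, immediate early and heat shock genes, extracellular matrix, candidate modifiers of metastasis, and glutathione and xenobiotic enzymes. Called genes were tested per chromosome with Fisher's exact test (scipy 1.17.1) and for neighbours with 10000 random draws of as many measured genes.

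The genes named in the text follow a rule fixed before the data were examined: the 12 largest differences in each direction among genes past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p and up to 8 members past the test, and the sex-linked genes. It gave 140 genes, of which 106 passed the test. Where another probe set of a gene past the test had the opposite sign, its difference is given.

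Alternatives chosen before the data were examined were quantile normalization, median centring, filters on dim probe sets, a variance trend with robust estimation, array weights, the replicate number as a block, leaving out each array, other thresholds, a test against a 1.2-fold change, the mean of a gene's probe sets, camera with a preset correlation of 0.01, fry, and other windows and family rules for neighbours. Alternatives chosen after seeing the data were the 3' to 5' index, the hybridization controls and the muscle list mean as covariates, removal of a trend with gene length (loess, span 0.5), draws matched on level in 20 bins, and restricting both tests of position to genes above the median probe set level. The calls used in that restriction came from a separate fit of those genes. The 3' to 5' index is the mean 3' minus 5' difference of actin, Gapdh and the 4 poly-A spikes.

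The steps were tested on simulated data with the spread of the real arrays. Over 18193 simulated genes with 200 changed, limma recovered 50% of 1.5-fold and 87% of 2-fold changes, with 7 false among 144 calls. The changed genes were drawn from brighter genes only, so these shares do not hold for dim genes. A list raised by a known amount passed camera (adjusted p = 0.0012) and 0 of 20 unchanged lists did. The genes were simulated without correlation between them, so this does not show how camera performs on the correlated real lists.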

Results

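Gene expression was measured in bone marrow of adult female mice from a pair of outcrosses that share the FVB/NJ parent. There were 3 arrays from (AKR/J x FVB/NJ)F1 animals, called AKR F1 here, and 3 from (DBA/2J x FVB/NJ)F1 animals, called DBA F1 here. The question was which genes differ in their basal level between these genotypes. Bone marrow holds developing red cells, granulocytes, monocytes, lymphocytes and platelet precursors beside stroma and bone cells, so a difference in a transcript can be one of level per cell or of cell number. The 6 arrays had medians from 5.14 to 5.19 on the log2 scale, and their number limits the precision of every value below. Nothing in the labels says which array came from which animal, so the p-values measure the spread between these samples. All differences are AKR F1 minus DBA F1 on the log2 scale, given with the standard error of limma's fit, and each gene is read from its brightest probe set.

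Arrays of the same group were more alike than arrays of different groups. Correlations across probe sets, which are not independent replicates, lay between 0.9936 and 0.9961 within AKR F1 and between 0.9906 and 0.9930 within DBA F1, against 0.9791 to 0.9880 between the groups. The first principal component of the genes (55.7% of the variance) separated the groups. On the second (18.6%) DBA F1 replicate 1 stood apart at -26.3, against 5.2 and 16.1 for DBA F1 replicates 2 and 3 and -2.5 to 5.2 in AKR F1. Xist, the RNA of the inactive X chromosome, was high in both groups, at 11.90 ± 0.20 and 11.53 ± 0.30 (mean ± SD, n = 3 each), and this difference did not pass the test (adjusted p = 0.16 in limma). Its other probe sets differed by -0.53 and -1.59, and the second of these passed the probe set test (adjusted p = 0.0076 in limma). The Y-linked genes Kdm5d, Uty and Eif2s3y had means between 2.83 and 3.59 in both groups, below the lower quartile of every array. Tsix, the antisense partner of Xist, was at 3.41 in AKR F1 and differed by -0.10.

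The marrow of the 2 crosses differed in many transcripts, most of them by less than 2-fold. Of 18193 genes, 1673 were higher in AKR F1 and 1098 were lower, 2771 in all, with a median absolute log2 difference of 0.52. Only 154 of these differed by 2-fold or more, 84 higher and 70 lower. The largest rises were in Hnrnpl, which encodes an RNA-binding splicing factor, and Npy, which encodes neuropeptide Y. The largest falls were mostly in genes of the contractile apparatus of skeletal muscle. At the level of 45037 probe sets, 5541 passed the limma test, 2509 higher and 3032 lower. In 2769 of the 2771 genes the 3 arrays of one group all lay above those of the other, as they did for 36.7% of all genes, where chance gives 10%. The gene count fell to 1396 without AKR F1 replicate 1, 685 without replicate 2, 793 without replicate 3 and 1585 without DBA F1 replicate 2, and the probe set count to 1885 and 1683 without AKR F1 replicates 2 and 3 and to 2950 without DBA F1 replicate 2. Controls added during processing also separated the groups, as given further on, and with a control measure as a covariate 21 genes (3' to 5' index) or 1 gene (hybridization controls) passed. In these fits 2771 and 2751 of the 2771 genes kept their sign, while the standard error rose to a median of 1.63 and 2.59 times its value.

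Among the 12 largest rises, Hnrnpl was at 9.65 ± 0.15 in AKR F1 and 5.34 ± 0.63 in DBA F1, a difference of 4.31 (SE 0.27, adjusted p = 0.00028 in limma). Its other, dimmer probe set differed by 0.15 and did not pass. Strain variants under the probes were not analysed here, so a difference at 1 of several probe sets, as in Hnrnpl and Alyref, is uncertain as a difference in transcript level. Npy, Prss22, H2-Q10, Scgb1a1, Redrum, Stard10, Ccar2, Sdf2l1 and Spen each have only 1 probe set with a single symbol. For these no other probe set can check the difference, and the same uncertainty holds. Npy was at 8.88 ± 0.26 against 4.82 ± 0.16, which is 16.8-fold higher (adjusted p = 1.9e-05 in limma). Prss22, a serine protease gene, was 8.76-fold higher. BC018473 and H2-Q10, a nonclassical MHC class I gene, were higher by at least 2.96 and 2.92, which are lower bounds because their DBA F1 means of 3.71 and 3.98 lay near the lower quartile of the arrays. The second probe set of BC018473 lay near the floor of the arrays and differed by -0.04. Redrum, a long noncoding RNA of red cell precursors, was 4.19-fold higher, and Stard10, which encodes a lipid transfer protein, was 3.18-fold higher at a level of 10.80. Alyref, a factor of mRNA export, differed by 1.71 at its brightest probe set and by -0.33 at the other, which did not pass. Ccar2, Sdf2l1 and Spen were 3.05-fold, 3.02-fold and 2.88-fold higher. Scgb1a1, the secretoglobin of airway club cells, varied most within a group (6.02 ± 1.44 in AKR F1), and its adjusted p of 0.042 in limma passed in 2 of the 6 fits that left out 1 array. The other 11 of these genes passed in all 6.

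**Figure D1:**
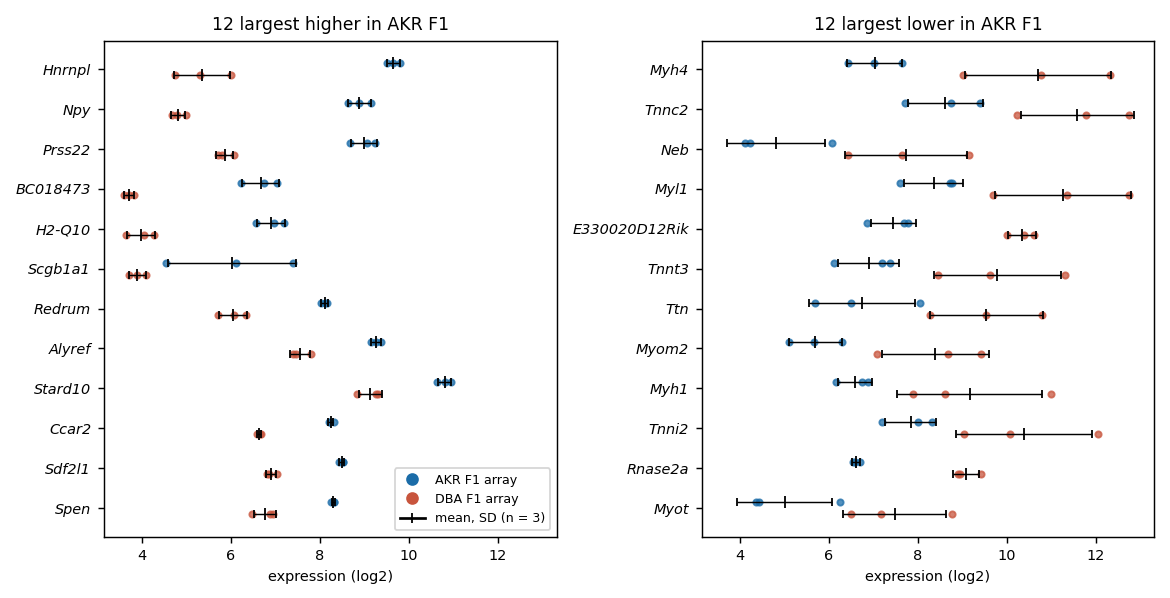
Log2 expression in each array for the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in AKR F1 against DBA F1, with dots for arrays and black marks for the mean and SD of 3 arrays. Npy lies at 8.88 against 4.82 with little spread, while Myh4 spreads widely in DBA F1 around its mean of 10.70.

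Of the 12 largest falls, 10 were in muscle genes. Myh4, a fast myosin heavy chain, was at 7.03 ± 0.61 in AKR F1 and 10.70 ± 1.65 in DBA F1, a difference of -3.67 (SE 0.70, adjusted p = 0.014 in limma). Tnnc2 (-2.97), Neb (-2.93), Myl1 (-2.91), Tnnt3 (-2.89), Ttn (-2.79), Myom2 (-2.70), Myh1 (-2.58), Tnni2 (-2.55) and Myot (-2.47) were the others, with adjusted p from 0.016 for Myom2 to 0.036 for Myh1 in limma. The skeletal muscle list had 9 of 20 measured members lower and none higher, 14 lower when adjusted over the list alone, and a median of -2.33. With an estimated correlation between its genes, which was 0.72, the list did not pass (adjusted p = 0.96), and with a preset correlation of 0.01 it did (adjusted p = 1.4e-08). The spread between arrays was wide: the mean of the list was 7.39, 8.16 and 6.93 in AKR F1 replicates 1 to 3 and 10.97, 8.52 and 9.18 in DBA F1. No member passed with a variance trend and robust estimation or without AKR F1 replicate 3, 1 passed without replicate 1, 3 without replicate 2 and 4 without DBA F1 replicate 3.

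The 2 largest falls outside muscle were far more even between arrays. E330020D12Rik was at 7.45 ± 0.50 in AKR F1 and 10.34 ± 0.31 in DBA F1 (difference -2.89, SE 0.25, adjusted p = 0.0012 in limma). Rnase2a, of the eosinophil-associated ribonuclease family, was at 6.62 ± 0.09 against 9.09 ± 0.29, a difference of -2.47 (adjusted p = 0.00024 in limma). Both passed in all 6 fits that left out 1 array. Each has only 1 probe set with a single symbol, so the limit on strain variants under the probes holds for them too. Ribonuclease genes of this family are close copies of each other, so the probe set may read more than 1 of them.

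None of the 25 gene lists fixed before the data were examined passed camera with an estimated correlation (0 at an unadjusted p under 0.05), while camera with a preset correlation and fry, which tests whether the genes of a list move one way, each called 1. The preset test called skeletal muscle, and fry called the glutathione list (adjusted p = 0.049). Camera compares the members of a list with all other genes, and the median difference over all genes was 0.06. Its direction can therefore be down for a list whose median or mean lies a little above 0. The group accounts that follow therefore rest on single genes, and their counts are of members past the gene test. For comparison, 15.3% of the measured genes with a position outside the Y chromosome passed. A separate fit of only the genes above the median probe set level, with its own adjustment, gave 25.6%. In the main test 2579 of those 11549 genes passed. Counts near these shares and medians near 0.06 do not set a list apart from other genes.

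Red cell genes were higher in AKR F1 where they differed. Of 32 measured erythroid genes 12 were higher, none was lower and 20 did not pass, with 13 higher when adjusted over the list alone. The median was 0.21, and the list had adjusted p = 0.97 with an estimated correlation. Cpox, an enzyme of heme synthesis, was 2.26-fold higher (10.21 ± 0.31 against 9.04 ± 0.27, adjusted p = 0.0079 in limma). Its other probe sets differed by 0.22, which did not pass the probe set test, and by 0.77, which did. Icam4, an adhesion molecule of red cells, was 1.65-fold higher, and Gata1, the transcription factor of red cell and platelet precursors, was higher by a log2 difference of 0.68. Nfe2, Sptb, Tspan33, Tal1 and Fech were higher by 0.64, 0.59, 0.57, 0.46 and 0.45. Without AKR F1 replicate 1, 2 or 3, the count of 12 became 7, 2 and 2, and with the mean of all probe sets of a gene 8 were higher and 2 lower. A second probe set of Fech differed by -0.30 and one of Sptb by -0.03, and neither passed.

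Interferon-induced genes showed the largest count, in the list with the most measured members, but not the largest share. Of 38 measured, 13 were higher in AKR F1, 2 were lower and 23 did not pass, with a median of 0.18 and adjusted p = 0.97 for the list with an estimated correlation. Adjusted over the list alone, 13 were higher and 4 lower. Of the 2'-5' oligoadenylate synthetase genes, which act in the antiviral response, Oas3 was 2.15-fold higher (7.84 ± 0.13 against 6.73 ± 0.14, adjusted p = 0.0020 in limma), Oas1a 1.93-fold, Oasl1 1.49-fold and Oas2 1.43-fold. These Oas genes all lie on chromosome 5, and whether they differ independently of each other was not tested. Ifi27l2a was 1.91-fold, Bst2 1.67-fold and Ifit1 1.58-fold higher. Samd9l went the other way, at 9.37 ± 0.13 against 9.88 ± 0.09. The number higher became 7, 8 and 7 without AKR F1 replicates 1, 2 and 3.

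Granulocyte genes were covered by 2 lists. Of 10 genes of primary granules and their precursors 3 were higher and none lower (median 0.39, adjusted p = 0.97 with an estimated correlation): Cebpa, a transcription factor of the granulocyte lineage, was 1.86-fold higher, Elane, the gene of neutrophil elastase, 1.76-fold and Nkg7 1.67-fold. Of 27 genes of secondary granules and maturation 1 was higher and 4 were lower, with 2 and 5 when adjusted over the list alone. Itgam, an integrin chain of myeloid cells, was at 8.26 ± 0.59 against 9.26 ± 0.28, and the formyl peptide receptor gene Fpr2 differed by -0.64, Clec4e by -0.52 and the chemokine receptor gene Cxcr2 by -0.49, and Hp, the gene of haptoglobin, was 1.26-fold higher. For this list the median was 0.14, the mean 0.06 and the direction of camera down. Its adjusted p was 0.97 with an estimated correlation, and the difference between the 2 lists was not tested. Without AKR F1 replicates 1, 2 and 3 the primary granule count became 1, 0 and 1 and the secondary granule count 3, 0 and 0. It was 5 for the primary list without DBA F1 replicate 1, and for the secondary list 1 and 2 without DBA F1 replicates 2 and 3. Without DBA F1 replicate 1 the secondary list turned from 1 higher and 4 lower to 4 higher and 1 lower, and without DBA F1 replicate 2 its 1 call was higher.

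Macrophage genes included the 3 chains of complement C1q. C1qc was 1.93-fold, C1qb 1.68-fold and C1qa 1.57-fold higher in AKR F1, as were the scavenger receptor gene Marco (1.85-fold) and Mertk (1.32-fold). The other probe sets of C1qb differed by 0.29 and 0.17, and neither passed. Of the 6 fits that left out 1 array, C1qa, C1qb and Mertk passed in 1, 2 and 1, and C1qc and Marco in 5 each. F13a1, the gene of a coagulation factor chain, differed by -0.57 and passed in all 6 fits that left out 1 array. In all, 5 of 28 monocyte and macrophage genes were higher and 1 was lower (median 0.08), with 7 and 3 adjusted over the list alone. This count of 6 became 3 and 1 without AKR F1 replicates 2 and 3, and without replicate 3 the 1 call was lower. Of 16 genes of eosinophils, basophils and mast cells 1 was higher, Hdc (1.61-fold), of 13 dendritic cell genes 1, Bst2, and of 14 osteoclast genes none passed. Acp5 differed by 0.71 in the osteoclast list (adjusted p = 0.063 in limma). The counts of these 3 lists were the same adjusted over the list alone, and all 4 lists had adjusted p = 0.97 with an estimated correlation. Hdc did not pass without any 1 of the AKR F1 arrays. With the mean of a gene's probe sets the eosinophil, basophil and mast cell list had 0 higher and 1 lower. Its count became 2 without DBA F1 replicate 2 or 3, and the dendritic cell count 2 without DBA F1 replicate 1. In the osteoclast list 2 genes were higher without DBA F1 replicate 1 and 1 was lower without replicate 2.

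Lymphocyte genes moved in both directions. In B cells, Ms4a1, which encodes CD20, was at 8.80 ± 0.26 against 9.79 ± 0.14 and Ebf1, a transcription factor of the lineage, at 7.90 ± 0.30 against 8.76 ± 0.18 (adjusted p = 0.0060 and 0.013 in limma). Cd79a, a chain of the B cell receptor, was higher by 1.32 in AKR F1 (10.63 ± 0.14 against 9.31 ± 0.74), a call lost without any 1 of the AKR F1 arrays. These were the 3 of 26 B cell genes past the test, and the list had a median of 0.07, a mean of 0.02 and a direction of down in camera. Of 13 plasma cell genes 3 were higher, Creld2, Edem1 and Tnfrsf17, and 3 lower, Igha, Jchain and Tnfrsf13b, with camera pointing down where the median (0.14) and mean were above 0. The T cell genes Cd3e and Cd4 were higher by 0.56 and 0.38, 2 of 19. Among 17 genes of NK cells and cytotoxic granules 3 were higher, Nkg7, Klrg1 and Ctsw, and 2 lower, the granzyme genes Gzma (-0.83) and Gzmb (-0.42). The list of NK gene complex receptors also holds related lectins such as Clec2d, which is not itself a receptor of NK cells. Of its 21 measured genes, Klrg1 was higher and Clec2d lower, by -0.81. Adjusted over the list alone, the counts were unchanged for B, plasma and T cells, 5 higher and 2 lower for NK cells and 0 higher and 1 lower for the receptors. With an estimated correlation the adjusted p was 0.82 for T cells and the receptors and 0.97 for the others. Without AKR F1 replicates 1, 2 and 3 the plasma cell count became 0, 1 and 0, the NK cell count 2, 1 and 3, and the T cell and receptor counts 1 each. Without DBA F1 replicate 2 the counts of plasma cells, NK cells, T cells and receptors were 2, 2, 1 and 1, and without replicate 3 those of plasma cells and NK cells were 2 and 3. Without DBA F1 replicate 1 the plasma cell list had 4 higher and 0 lower. The NK cell list turned to 0 higher and 1 lower without AKR F1 replicate 2 and to 1 higher and 2 lower without AKR F1 replicate 3 or with a variance trend and robust estimation.

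Antigen presentation genes lay at both ends. H2-Ea, the alpha chain of the class II molecule E, was at 8.56 ± 0.18 in AKR F1 and 10.22 ± 0.25 in DBA F1 (difference -1.65, SE 0.14, adjusted p = 0.0013 in limma). A second probe set of H2-Ea differed by -3.74 and another, near the floor, by 0.02. Cd74, the class II invariant chain, was 1.48-fold higher, and these were the 2 of 11 class II genes past the test. The class II list had a median of 0.06, a mean of -0.02 and a direction of up in camera. Of 16 genes of class I and antigen processing, H2-Q10, Tap2 (1.58-fold) and Psmb9 (1.49-fold) were higher and Erap1 was lower by -0.33. Adjusted over the list alone, class II had 3 higher and 1 lower and class I had 3 and 1, and both lists had adjusted p = 0.97 with an estimated correlation. Without each AKR F1 array, 1 gene of class I and 1 of class II passed, and without DBA F1 replicate 2 or 3, 2 of class I and 1 of class II. H2 genes are close copies of each other and differ between strains, so these values are uncertain as levels of single genes.

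Of 29 genes of glutathione and xenobiotic enzymes 5 were higher and none lower: Gstm5 (1.44-fold), Gstp1 (1.40-fold), Cbr1 (1.32-fold), Ephx1 (1.27-fold) and Gpx4 (1.26-fold). The count was the same adjusted over the list alone, the adjusted p was 0.82 with an estimated correlation, and 2, 1 and 0 passed without AKR F1 replicates 1, 2 and 3 and 2 without DBA F1 replicate 2. In the list of immediate early and heat shock genes, Klf2, Jund, Btg2 and Zfp36 were 1.77-fold, 1.59-fold, 1.49-fold and 1.35-fold higher and Hsp90aa1 was lower by -0.37, 5 of 27. Lipe and Pnpla2, which encode fat-cell lipases, and Acaca were higher, 3 of 16 adipocyte genes. Gp9 and Gp5, platelet glycoprotein genes, were higher, 2 of 18 (median -0.05, mean 0.05, direction down in camera). Of 37 proliferation genes, Foxm1 was higher and the kinesin genes Kif11 and Kif23 were lower. Of 32 genes of stroma, bone and endothelium 5 were higher, Eng, Cdh5, Col6a1, Kdr and Col5a1, and 2 lower, Mmp13 (-0.79) and Pdgfra (-0.63). Of 36 matrix genes, Col6a1 was higher and Thbs1 (-0.78), Mmp13, Nid1 and Lamb1 were lower, and in both lists the median and mean were above 0 while camera pointed down. Hoxa9 was lower, 1 of 22 genes of stem and progenitor cells, and in that list the median was 0.005 while the mean and camera's direction were below 0. None of 9 candidate modifiers of metastasis passed at its brightest probe set. For Arid4b that probe set differed by -0.20. However, 2 dimmer ones differed by -1.31 and -0.54 and passed the probe set test (adjusted p = 0.0031 and 0.030 in limma). Sipa1 differed by 0.47 (adjusted p = 0.15 in limma) and that list's median and mean were above 0 with camera pointing down.

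Adjusted over the list alone, the counts higher and lower were 4 and 1 for immediate early genes, 5 and 1 for adipocytes, 1 and 0 for platelet genes, 0 and 2 for proliferation, 5 and 3 for stroma, 1 and 4 for matrix, and 0 for progenitors and for metastasis modifiers. Each of these 8 lists had adjusted p = 0.97 with an estimated correlation. Without AKR F1 replicates 1, 2 and 3 the immediate early count became 2, 1 and 2, the stroma count 4, 2 and 1, the matrix count 3, 2 and 2, the platelet count 1, 0 and 0 and the proliferation count 1 each time. Without AKR F1 replicate 2, AKR F1 replicate 3 or DBA F1 replicate 2, all calls left in the stroma list were lower. With quantile normalization the proliferation list had 3 higher and 2 lower and the progenitor list 1 higher and 0 lower, and with the mean of a gene's probe sets the platelet list had 2 higher and 3 lower. Hoxa9 did not pass without any 1 of the AKR F1 arrays, nor without DBA F1 replicate 2 or 3. The adipocyte count became 0 and 1 without AKR F1 replicates 2 and 3 and 1 without DBA F1 replicate 2. Without DBA F1 replicate 1 stroma had 11 calls, proliferation 5 and progenitors 3, and matrix turned from 1 higher and 4 lower to 7 higher and 5 lower. A dimmer probe set of Hoxa9 differed by 0.04 and one of Edem1 by -0.004. Acaca, Cdh5, Foxm1, Hsp90aa1, Lamb1, Lipe, Myh1, Myom2 and Ttn also had a dim probe set of the opposite sign, with differences from -0.04 to 0.18, and none of these passed. Without DBA F1 replicate 2 stroma had 2 and immediate early genes 3, and without replicate 3 these had 3 each, matrix 3 and platelet genes 1.

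**Figure D2:**
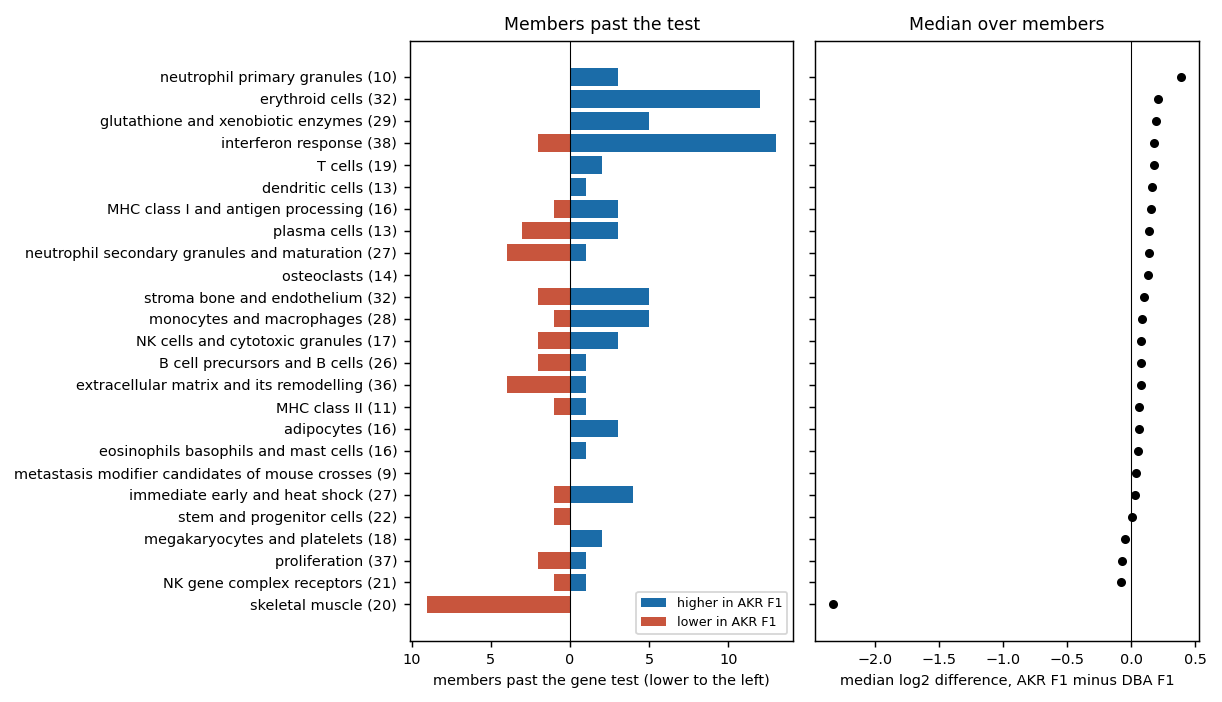
Members of each of the 25 lists past the gene test, with those higher in AKR F1 drawn to the right and those lower to the left (left panel, number measured in parentheses), and the median log2 difference over the measured members (right panel). Interferon response (13 higher, 2 lower) and erythroid cells (12 higher) hold the most calls upward, and skeletal muscle (9 lower) lies apart at a median of -2.33.

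Because the groups differ in 1 parental genome, the place of the called genes was compared with that of all 18030 measured genes with a position. On chromosome 11, 273 of 1443 genes passed (18.9%, compared with genes elsewhere by Fisher's exact test, two-sided, adjusted p = 0.0024), and on chromosome 19, 121 of 609 (19.9%, adjusted p = 0.021). No other chromosome passed. Neither passed with the mean of a gene's probe sets, without AKR F1 replicate 1 or without replicate 3, where no chromosome did, and 5 chromosomes passed without DBA F1 replicate 1. Of the called genes, 83.4% had another called gene among the 5 measured genes on either side, against 80.9% in random draws of as many genes (one-sided permutation p = 0.00050). With 2 genes on either side these shares were 54.5% and 48.5%. There was no excess with 10 genes on either side (96.0% against 96.2%) or over genes above the median probe set level (94.1% against 94.7%). Without AKR F1 replicate 2, with 683 called genes, the shares were 34.99% and 31.9% and the test did not pass (permutation p = 0.088), nor did it without DBA F1 replicate 1 (86.5% and 86.1%, permutation p = 0.24). Over those brighter genes chromosome 7 alone passed (adjusted p = 0.0081, Fisher's exact test).

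Control transcripts added during processing differed between the groups as well. The 9 hybridization control probe sets averaged 10.53 ± 0.10 in AKR F1 and 11.11 ± 0.20 in DBA F1 (n = 3 each), and each was higher in all DBA F1 arrays than in all AKR F1 arrays. The 3' probe sets of the 4 poly-A spikes, which are added to the RNA before labelling, averaged 8.05 ± 0.08 against 7.47 ± 0.10. The mean 3' to 5' difference over 6 control transcripts was 1.69 ± 0.40 against 1.12 ± 0.10, with AKR F1 replicate 1 at 1.25 next to DBA F1 replicate 1 at 1.23. These are the 4 poly-A spikes and, from the sample itself, actin and Gapdh. The difference grows as labelled fragments become shorter and, for actin and Gapdh, as sample RNA is degraded. Each of these 3 measures had a two-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. Of the 6 parts of the third, actin and the lys spike overlapped between the groups. Outside that index, the 3' to 5' difference of the sample's own transferrin receptor transcript was 3.39 ± 0.23 in AKR F1 against 2.56 ± 0.09. That of pyruvate carboxylase was 2.22 ± 0.19 against 1.46 ± 0.28, and neither overlapped. The hybridization controls and the spikes do not come from the mice, so a difference in them is not one of mouse transcripts. Their values were normalized together with the sample signal. They therefore do not show whether processing or the sample RNA was the source.

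**Figure D3:**
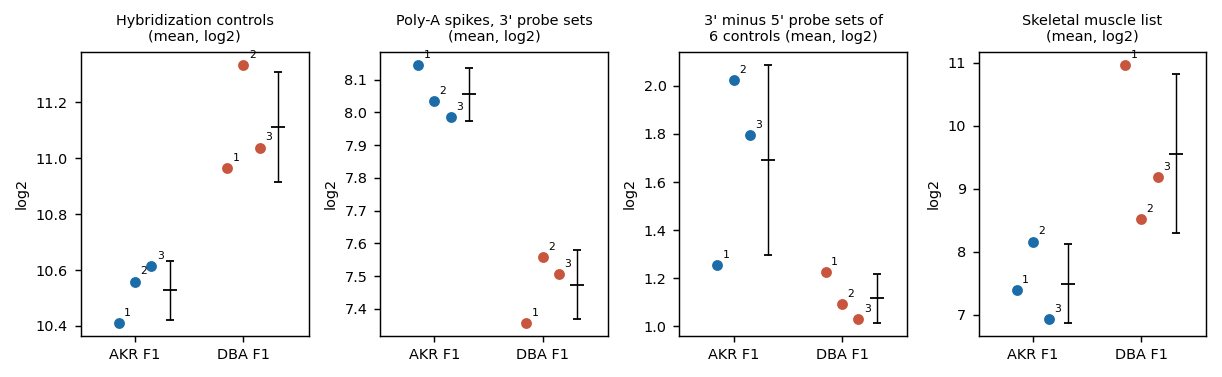
Array means on the log2 scale of hybridization controls, 3' probe sets of poly-A spikes, the 3' minus 5' difference of 6 control transcripts, and the skeletal muscle list, with 1 dot per array numbered by replicate and the mean and SD of 3 arrays beside them. The groups do not overlap in any of the 4 measures, and AKR F1 replicate 1 lies at 1.25 in the third, close to DBA F1 replicate 1 at 1.23.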

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

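Of the tests in this part, those of chance splits of the gene count, of gene length and of 3' bias in other probe sets were written before their results were seen, and all others after. The covariate fits were also chosen after seeing the data.

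Measures from the control probe sets, which were left out of the gene tests, separated the groups. The hybridization controls were higher in DBA F1 by 0.58, the 3' probe sets of the poly-A spikes were higher in AKR F1 by 0.58, and the 3' to 5' index was higher in AKR F1 by 0.58. Among the 9160 probe sets without a gene symbol here, 540 passed the limma test, 242 higher and 298 lower.

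The first pattern is the count of 2771 genes. The 10 splits of the arrays into 3 and 3 are too few for a share under 0.05: 1 of the 10, the real one, gave as many genes, and the highest other split gave 1. For the 5541 probe sets it was 1 of 10 too, with a highest other of 0, and for gene lists the real split and all 10 gave 0. A trend with genomic gene length existed: of 5 groups of genes by length, the shortest held 394 higher and 70 lower, the longest 206 and 301. Removing it from each array left 2615 calls, 2380 of them shared with the 2761 before, so this trend does not account for most calls. The group medians spanned only 0.08, against a median absolute difference of 0.52 for called genes, so the removal could move the count little. It therefore does not speak against a bias in labelling, and the distance of probe sets from the 3' end was not tested.

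What stays open for that count is the labelling and the array set. All 9 hybridization control probe sets were higher in all DBA F1 arrays, so arrays handled as 1 set per genotype cannot be told apart from the genotypes. Over genes called without it, AKR F1 replicate 1 lay at a median position of 0.83, and its 3' to 5' index lay at 0.17. On this scale 0 is the DBA F1 mean and 1 the other AKR F1 arrays. AKR F1 replicates 2 and 3 lay at 1.002 and 0.954 over genes called without each, with the index at 2.22 and 1.298. The order of these positions follows that of the index, so 3' bias may contribute to the count. DBA F1 replicate 2, with the highest hybridization controls (position 1.70), lay at 0.82 over genes called without it, but each of these positions rests on 1 array and both control measures separate the groups, so neither measure can be told apart from genotype. The fits with them as covariates decide nothing, since the median absolute difference of the 2771 genes went from 0.52 to 0.47 (index) and 0.57 (hybridization controls) and the median standard error rose from 0.11 to 0.17 and 0.27, which ended the calls. The different parents remain an untested biological explanation.

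The second pattern is the lower level of muscle transcripts in AKR F1. None of the 20 genes belongs to another of the lists, and no sort or gate is named that would remove muscle. In DBA F1, 80% of the list had the arrays in the order 1, 3, 2, but this order was read from the same values and the genes are correlated, so it does not speak for muscle tissue in the sampled marrow over another source. Only 12 of the 20 genes were lower in all AKR F1 arrays than in all DBA F1 arrays: Acta1 was at 10.9 and Ckm at 9.25 in AKR F1 replicate 2, above 10.8 and 9.18 in DBA F1 replicate 2, and both overlapped (two-sided exact permutation p = 0.2). Among the DBA F1 arrays, which share a genotype, the list mean ran from 8.52 to 10.97, so genotype is not the only source of its spread. For the difference between the groups, muscle in the dissected samples and a difference between genotypes stay open.

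The third pattern is a split between the brightest and the other probe sets, taken as 2 classes. The brightest include those of genes with only 1 probe set. Within the 1647 called genes with more than 1, 599 had another called the same way, 49 the opposite way and 1015 no other called. Among brightest probe sets 60.2% of the calls were higher in AKR F1 (1437 against 951), and among the other probe sets 31.2% (778 against 1718). Level does not account for it: in the upper 2 of 5 level groups the gap was at least 20.4 percentage points. Over other probe sets called lower without it, AKR F1 replicate 1 lay at a median position of 0.66, against 1.25 and 0.91 for replicates 2 and 3, an order that follows the 3' to 5' index, so 3' bias may contribute and cannot be told apart from genotype. No biological explanation was tested, and strain variants under the probes were not analysed here.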

How the results depend on the processing

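The covariate fits, the length trend, the level-matched draws and the dim filter on positions were chosen after seeing the data. Leaving out 1 array gave 1683 to 5581 probe sets, 685 to 3248 genes, 0 gene lists in each fit, 0 to 5 chromosomes and a share with a called neighbour of 34.99% to 86.5%, with fewer arrays as part of the cause. An adjusted p under 0.01 gave 1214 probe sets and 526 genes, one under 0.10 gave 8489 and 4243, and a test against a 1.2-fold change gave 901 and 237, by construction. The 3' to 5' index as a covariate gave 112 probe sets and 21 genes, the hybridization controls 5 and 1, and the muscle mean 210 and 239; each covariate differs between the groups, takes 1 degree of freedom and raises the standard errors. With the muscle mean as a covariate, the calls higher and lower were 7 and 1 for matrix and 7 and 0 for stroma. They were 0 and 0 for erythroid cells and 1 and 0 for interferon response in that fit. Camera with a preset correlation and fry each called 1 list. With the mean of a gene's probe sets 0 chromosomes passed, and over genes above the median probe set level 1 did; the cause was not tested. There was no neighbour excess with 10 genes on either side (96.0%), with calls at an adjusted p under 0.10 (92.3%) and over genes above the median probe set level (94.1%), where nearly all genes have a called neighbour, and it held against level-matched draws (83.4% against 81.5%, permutation p = 0.0035). The other settings gave counts of probe sets and genes within 1.5 times of the main ones, but not counts of calls per gene list. With array weights these became, as higher and lower, 5 and 5 (matrix), 8 and 2 (monocytes), 3 and 5 (secondary granules), 4 and 1 (adipocytes), 2 and 3 (proliferation), 2 and 2 (platelets), 2 and 2 (progenitors), 2 and 0 (osteoclasts) and 2 and 0 (dendritic cells). Quantile normalization gave 5 and 0 (adipocytes), 3 and 2 (proliferation) and 2 and 0 (eosinophils, basophils and mast cells). Median centring gave 2 and 1 (NK cells), 0 and 3 (secondary granules), 0 and 1 (class II) and 1 and 0 (platelets). The variance trend gave 1 and 2 (NK cells), 0 and 1 (NK receptors) and 0 and 0 (muscle). The mean of a gene's probe sets gave 2 and 3 (B cells), 2 and 3 (platelets), 0 and 3 (progenitors) and 0 and 1 (metastasis modifiers). Leaving out probe sets under the median level gave 5 and 1 (adipocytes), 2 and 3 (proliferation) and 1 and 1 (progenitors). Removing the length trend gave 2 and 0 (class I), 0 and 1 (class II), 0 and 1 (NK receptors), 0 and 3 (secondary granules), 1 and 0 (platelets) and 1 and 1 (progenitors). The cause was not tested. The replicate numbers share no sign of pairing (correlations of deviations 0.01, -0.06 and 0.07, and not every array correlated best with its own number), and the replicate block gave 5321 probe sets and 2357 genes, with 3 and 0 calls for glutathione, 2 and 0 for class I, 2 and 1 for NK cells, 0 and 1 for NK receptors, 1 and 0 for platelets and for osteoclasts, and 1 and 1 for progenitors. Of 106 named genes past the test, 33 passed in every fit that left out 1 array, 102 with quantile normalization, 94 with median centring and 86 with a variance trend and robust estimation, and none of them reversed. Both pseudocounts in the plan were not run, since the table is on a log2 scale. Signal over background limits the dimmest genes, for which no detection calls were used here.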

Other observations

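The tests by chromosome of median difference were looked at only after the data were seen and are given as values. Over genes above the median probe set level, the median log2 difference was 0.18 on chromosome 7, 0.15 on chromosome 17 and 0.14 on chromosome 11, and it was -0.08 on chromosome 13 and on the X chromosome. On chromosome 7, 199 called genes were higher in AKR F1 and 46 lower, and on chromosome 13, 26 and 69.

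Of the 1647 called genes with more than 1 probe set, 599 had another probe set called the same way, 49 had one called the opposite way and 1015 had no other probe set past the test.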
